A study of Mus musculus with 4 samples.

How the data were processed

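Nuclei were isolated from the brains of wild-type (WT) mice and mice with a knockout (KO) of Fmr1, the gene whose loss underlies Fragile X syndrome, at postnatal day 7, per the labels' protocols. Single-nucleus libraries were made with inDrops, a droplet method in which each nucleus receives a barcode and each captured transcript a unique molecular identifier (UMI) near its 3′ end. The tissue was brain, with no region named in the labels, and no treatment was applied. The 4 GEO samples are sequencing lanes of a pool of all libraries, so none of them belongs to a genotype and all 4 were left unassigned. The genotype, a batch and a library number were instead read from words in the name that each nucleus carries in the tables. Those names give 32 libraries, 8 labelled WT and 8 labelled KO in each of 2 batches. The series description speaks of 16 libraries, 8 per genotype, as biological replicates, and what the batches were is not given in the sources used here. Since the names give more libraries than this, whether those of 1 batch and genotype came from separate animals is not certain. Nor is it certain that the 2 batches came from different animals. The 16 libraries per genotype may thus hold fewer biological replicates. The p-values measure the spread between libraries, which may be partly technical.

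The deposited tables hold raw UMI counts per gene and nucleus, without normalization, in 4 tables for the classes named by the authors as astrocytes, microglia, excitatory neurons and inhibitory neurons. Reads were converted with bcl2fastq and the genome build was mm10, per the submitters' processing notes. Demultiplexing and counting used the inDrops pipeline, per the labels. The versions of these tools, the annotation, the use of strand in counting, the filters on nuclei, the removal of doublets and the method of class assignment are not given in the sources used here. The nuclei were used as deposited, with no filter and no further clustering or doublet calling. The lowest total per nucleus was 251 UMIs in the astrocyte, microglia and inhibitory tables, whose totals reached 4965, 4394 and 4982 UMIs. No mitochondrially encoded gene was listed in any table. The excitatory table ends within a gene's values, so that only 10317 genes, the alphabetical first part up to Lce1a1, were complete and used, against 21511 genes in each other table. Excitatory values are therefore relative to the UMIs of these genes, and genes later in the alphabet were not analysed here for that class. Of the 21511 symbols, 21243 (98.8%) matched the GENCODE vM21 annotation of GRCm38, the assembly that mm10 names, and coordinates are 1-based from it.

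Nuclei are not replicates, so counts were summed per library and class. Libraries with fewer than 10 nuclei of a class were left out of its tests, which removed 4 libraries from microglia alone and left 15 labelled WT and 13 labelled KO. Genes were tested in each class alone with edgeR 4.0.16 (TMM scaling, filterByExpr, robust quasi-likelihood fit, genotype as the only term), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p given for a gene comes from this test unless another tool is named. Levels are CPM, counts scaled to the total of the class in the library, as mean ± SD over libraries, and errors of log2 fold changes are standard errors. A difference of the genotype effect between classes was tested pair by pair with a genotype by class term and library as a block. The 44 gene lists (pathways, cell-class markers and subtype genes) were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01 where at least 5 members were tested, adjusted over the lists of a class. Shares of nuclei and medians of UMIs or genes per nucleus were compared with two-sided permutation tests. These used 100000 permutations over all libraries, since the tables hold more libraries than the description gave and not all splits could be run, and all splits within a batch, called exact tests. Computations ran in R 4.3.3 and in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

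The tests, the gene lists, a set of other settings and the rule for named genes were fixed before the data were examined. The rule takes Fmr1, then for each class the 8 genes with the smallest p on each side of the comparison among those past the threshold with a mean of at least 5 CPM. It adds up to 4 members of each list past the threshold, up to 2 members of highest CPM beside a list, the 10 genes of smallest p where fewer than 5 pass, and the 5 genes of smallest p per pair of classes. Some genes that the rule names are not reported here. Those settings were DESeq2 1.42.0, limma-voom, other scalings, no filter on low counts, a stricter filter, another minimum of nuclei, a batch term (called the replicate block), 1 surrogate variable (sva 3.50.0), nuclei thinned to a common depth, each library without its deepest nucleus, and each library left out in turn. Chosen after the data were examined were fits within each batch, 4 sums with 1 per genotype and batch, the library number as a block, and the share of counts in genes of other classes as a covariate. Libraries of the same batch deviated together from their genotype's mean. Across genes the correlations were 0.63 in astrocytes, 0.61 in microglia, 0.63 in excitatory and 0.59 in inhibitory neurons. The replicate block therefore treats the batch as a shared factor of both genotypes, while the main test holds genotype alone.

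The fits were tested on simulated counts with the real means and library sizes, but without a batch effect. Their spread was the one left after the batch was fitted. In astrocytes the common dispersion was 0.0225 with the batch as a block and 0.0552 with genotype alone. The recoveries below therefore overstate what the genotype-only test can find at the real spread. Of genes changed 1.5-fold, edgeR recovered 77 of 90 in astrocytes, 20 of 31 in microglia, 84 of 97 in excitatory and 74 of 95 in inhibitory neurons, and of genes changed 2-fold it recovered 88 of 88, 28 of 28, 97 of 98 and 95 of 96. The interaction fit for astrocytes and inhibitory neurons recovered 72 of 140 differences of 1.5-fold and 140 of 144 of 2-fold. Of 88 named genes, 25 share exon sequence with another annotated gene, 19 of them with a gene on the opposite strand, and those values are uncertain to the extent that reads were split between the genes.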

Results

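The deposited nuclei came from brains of mice at postnatal day 7, in 32 libraries, 16 labelled WT and 16 labelled KO. Astrocytes made up 9984 nuclei (5550 labelled WT and 4434 labelled KO), microglia 833 (436 and 397), excitatory neurons 40501 (22536 and 17965) and inhibitory neurons 15881 (7952 and 7929). A median nucleus carried 440 UMIs in astrocytes, 387 in microglia, 794 in inhibitory neurons and 300 in excitatory neurons, the last over the first part of the gene list only. Summed over nuclei, a library held 38619 to 451793 UMIs of astrocytes and 2473 to 30527 of microglia. It held 199283 to 740478 UMIs of excitatory neurons and 93797 to 1081171 of inhibitory neurons. The microglial sums were thus the shallowest. In them 140 genes had enough counts to be tested, against 4306 in astrocytes, 4628 in excitatory neurons and 7551 in inhibitory neurons. Batch 2 held fewer nuclei than batch 1 in astrocytes (2667 against 7317), microglia (216 against 617) and inhibitory neurons (3405 against 12476), and about as many excitatory nuclei (20207 against 20294).

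**Figure D1:**
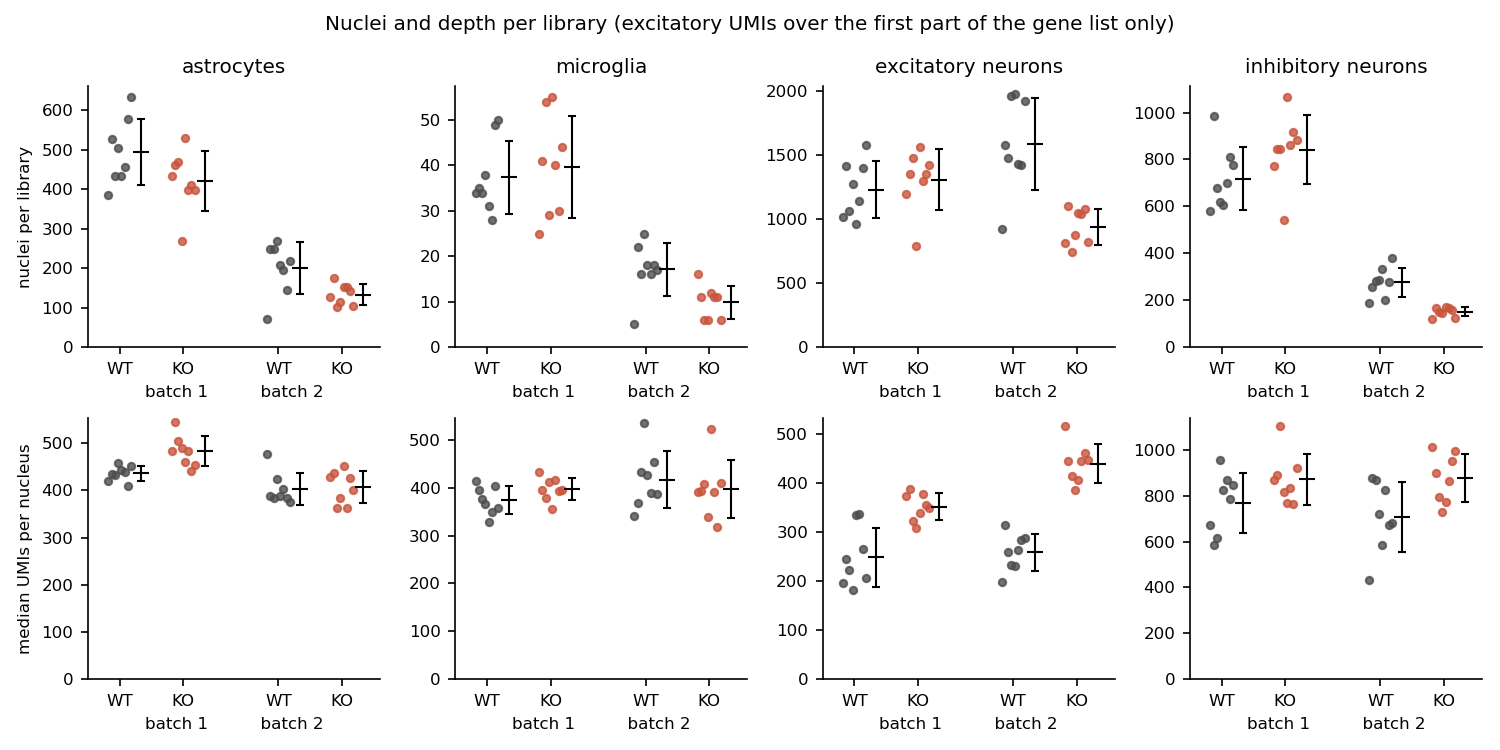
Nuclei per library (upper row) and the median of UMIs per nucleus (lower row) in each class; each dot is a library, grouped by batch and by the genotype word in its name, and the bar beside each group is the mean ± SD. Libraries labelled KO lie higher in UMIs per excitatory nucleus in both batches, and batch 2 has fewer nuclei in the other classes.

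Fmr1 encodes FMRP, an RNA-binding protein that regulates translation at synapses, and lies at X:68678541-68717963 on the forward strand. Its transcript was detected in both genotypes and did not pass the test in any class. In astrocytes it was at 90.1 ± 28.5 CPM in libraries labelled WT and 114 ± 38.3 CPM in those labelled KO (n = 16 and 16, log2 fold change 0.28 ± 0.17, adjusted p = 0.48). The values were 161 ± 36.4 and 152 ± 47.5 CPM in excitatory neurons (-0.07 ± 0.12, adjusted p = 0.86) and 82.5 ± 27.0 and 81.7 ± 29.7 CPM in inhibitory neurons (0.10 ± 0.15, adjusted p = 0.86). Microglia gave only 29 Fmr1 UMIs in all tested libraries, too few for a test. The labels do not state which part of the gene is disrupted, and a 3′ tag outside that part is no check of the genotype. The groups are therefore named throughout by the words in the nucleus names.

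**Figure D2:**
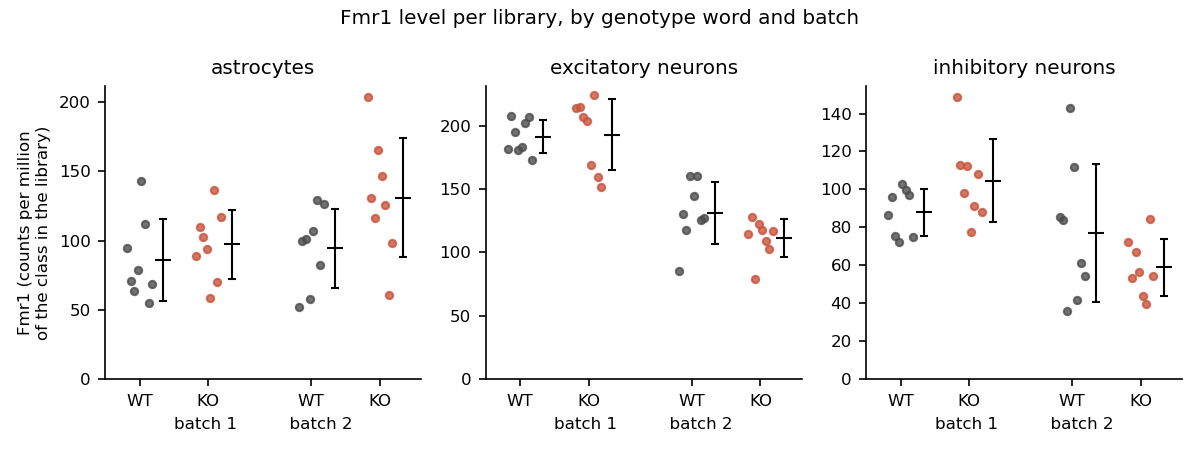
Fmr1 level in CPM of the class in the library, for astrocytes, excitatory neurons and inhibitory neurons; each dot is a library, grouped by batch and genotype word, with mean ± SD. The ranges of libraries labelled WT and KO overlap in each batch and class.

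The makeup of the nuclei was compared first, since it sets the depth of every other value. No class differed in its share of nuclei over all libraries (permutation tests, adjusted p = 0.98 for each of the 4). Astrocytes made up 14.7% ± 5.65 of nuclei in libraries labelled WT and 13.5% ± 2.96 in those labelled KO, and microglia 1.16% ± 0.414 and 1.16% ± 0.476 (n = 16 and 16). Excitatory neurons made up 62.9% ± 13.9 and 63.1% ± 13.6, and inhibitory neurons 21.2% ± 8.36 and 22.3% ± 10.4. Among nuclei of at least 500 UMIs the share was lower for astrocytes (-4.99 percentage points, permutation test, adjusted p = 0.0242) and microglia (-0.348, adjusted p = 0.0381) and higher for excitatory neurons (13.6, adjusted p = 0.0466). That of inhibitory neurons did not pass (-8.26, adjusted p = 0.0859). Excitatory nuclei labelled KO were deeper, so this limit keeps more of them and lowers the other shares, and these values are no measure of makeup apart from depth. The batches did not share the result over all nuclei. In batch 1 the astrocyte share was lower in libraries labelled KO, at 16.2% against 19.9% (exact permutation test, p = 0.00031, adjusted p = 0.0012, n = 8 and 8). The inhibitory share was higher there, at 32.3% against 29.0% (exact p = 0.0078, adjusted p = 0.016). In batch 2 the values were 10.7% against 9.47% (exact p = 0.146) and 12.3% against 13.4% (exact p = 0.163). Excitatory nuclei labelled KO were deeper, with a library median of 396 ± 56.3 UMIs against 253 ± 48.4 (permutation p = 1e-05, the smallest that 100000 permutations can give; exact p = 0.0016 in batch 1 and 0.00016 in batch 2). Inhibitory nuclei labelled KO were deeper as well, with 875 ± 104 against 739 ± 141 (permutation p = 0.0035, adjusted p = 0.0094; exact p = 0.115 and 0.0191). Astrocytes (445 against 420, p = 0.0987) and microglia (399 against 399, p = 0.98) did not pass by permutation test over all libraries. In batch 1 alone astrocytes labelled KO were deeper, by 46.9 UMIs (exact test, adjusted p = 0.0031) and 37.1 genes per nucleus (exact test, adjusted p = 0.0012). In batch 2 the differences were 3.38 UMIs and, in the opposite direction, -23.8 genes per nucleus (exact tests, adjusted p = 0.848 and 0.0952). Genes per nucleus were also higher in excitatory nuclei labelled KO (276 against 190, permutation p = 1e-05). Those of astrocytes (313 against 307, p = 0.756), microglia (283 against 291, p = 0.584) and inhibitory neurons (600.03 against 533, p = 0.0823) did not pass over all libraries. Permuted within batches, those of inhibitory neurons did (67.1 genes more, adjusted p = 0.0399), and in batch 2 alone those of microglia were lower, by -54.0 (exact test, adjusted p = 0.0382).

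Astrocytes are at the centre of the series' question of how glia take part in synaptic refinement. In libraries labelled KO the matrix genes Ncan and Ptprz1 rose, and Map1b and Vamp2 fell. Ncan (8:70093085-70120873), which encodes the matrix proteoglycan neurocan, rose from 3260 ± 390 to 4791 ± 1026.5 CPM, a log2 fold change of 0.57 ± 0.09 (n = 16 and 16, adjusted p = 7.8e-05). It lay above the WT median, here and below taken over both batches, in 16 of 16 libraries labelled KO. Ptprz1 (6:22875502-23052916), a receptor phosphatase that carries chondroitin sulfate, rose from 4418 ± 707 to 6342 ± 1117 CPM (0.54 ± 0.09, adjusted p = 7.8e-05). Map1b (13:99421446-99516540), a microtubule-associated protein whose mRNA FMRP binds, fell from 1691 ± 370 to 1088 ± 148 CPM (-0.62 ± 0.09, adjusted p = 7.2e-05, below the WT median in 16 of 16 libraries). Vamp2 (11:69088490-69092384), a vesicle protein of the release machinery, fell from 341 ± 71.7 to 215 ± 52.3 CPM (-0.65 ± 0.12, adjusted p = 0.0011).

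Among 4306 genes tested in astrocytes with edgeR, 90 passed, 47 higher and 43 lower in libraries labelled KO. With the batch as a block 356 passed, 180 higher and 176 lower, all 90 among them. The other higher genes of smallest p were Rsrp1 (0.66 ± 0.11), a nuclear protein gene, Pla2g3 (0.64 ± 0.12), a secreted phospholipase, Tia1 (0.51 ± 0.09), an RNA-binding protein of stress granules. They were followed by the laminin receptor subunit Itga6 (0.63 ± 0.12), the ubiquitin ligase adaptor Wsb1 (0.69 ± 0.13) and the glycosidase gene AI464131 (0.61 ± 0.12). The other lower genes of smallest p were the transcription factor Zfhx3 (-0.74 ± 0.14), the ankyrin Ank3 (-0.60 ± 0.13), the RNA-binding protein Elavl3 (-0.53 ± 0.12) and Fam102b (-0.55 ± 0.12). With them fell the elongation factor Eef1a1 (-0.38 ± 0.07) and Rps7 (-0.51 ± 0.12). Of the 47 higher genes 21 (44.7%) were at least 4 times as abundant in astrocytes as in any other class, against 5.81% of genes tested (odds ratio 14.2, 95% interval 7.47 to 26.7). Of the 43 lower genes 0 were as much more abundant in another class. At least 2 times as abundant in another class were 13 (30.2%), against 16.3% of genes tested (odds ratio 2.24, 95% interval 1.07 to 4.46, p = 0.0206). In these comparisons, here and below, genes later in the alphabet than Lce1a1 had no excitatory values to be set against. Each named gene past the threshold lay on its side of the WT median in at least 13 of 16 libraries labelled KO. Since the genes were chosen by p in the same libraries and the median pools both batches, such counts are no separate support. The size differed between the batches, as for Tnc (0.58 in batch 1 and 0.06 in batch 2), Zfhx3 (-0.39 and -1.40) and Ank2 (-0.05 and -0.78). With the libraries summed to 1 value per genotype and batch, edgeR passed 0 genes (647 at an unadjusted p under 0.05).

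The gene lists placed these changes in groups, with 7 of 19 tested lists past the threshold by camera. Cytosolic ribosomal proteins fell (median log2 fold change -0.29 over 32 tested members, adjusted p = 7.9e-12, and adjusted p = 0.012 with an estimated correlation). Lower members numbered 3 over all genes and 14 adjusted over the list alone, among them Rps23 (-0.41 ± 0.10), Rps14 (-0.45 ± 0.11) and Rps7. Genes of cholesterol synthesis rose (median 0.33, 16 tested, adjusted p = 3.2e-05, and adjusted p = 0.012 with an estimated correlation), with 2 members higher over all genes and 4 adjusted over the list alone. Msmo1 (0.51 ± 0.10), a sterol demethylating oxidase, passed, while Hmgcs1 was at -0.15 ± 0.15. Presynaptic release genes fell (median -0.21, 26 tested, adjusted p = 8.6e-05, and adjusted p = 0.0036 with an estimated correlation). Only Vamp2 passed in both adjustments, and the calcium sensor Syt1 (-0.20 ± 0.10) did not. These 3 calls hold with an estimated correlation. Genes of astrocyte transport and homeostasis rose (median 0.22, 18 tested, 3 higher over all genes and 9 adjusted over the list alone, adjusted p = 5.1e-05, and adjusted p = 0.054 with an estimated correlation). Members that passed were the glutamate transporter Slc1a3 (0.32 ± 0.07) and the glutamate receptor Grm3 (0.70 ± 0.20), which passed in only 18 of 48 alternatives.

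Synapse-organising factors of astrocytes rose (median 0.14, 14 tested, 3 higher in both adjustments, adjusted p = 0.0043, and adjusted p = 0.075 with an estimated correlation). The members that passed were the matrix genes Ncan, Bcan (0.33 ± 0.08) and Tnc (0.36 ± 0.09), whereas Sparcl1, a secreted synaptogenic protein and the most abundant member, was at -0.20 ± 0.17. Transcripts reported as bound by FMRP fell as a list (median -0.09, 33 tested, 3 lower over all genes and 4 adjusted over the list alone, adjusted p = 0.028, and adjusted p = 0.075 with an estimated correlation). Map1b, Ank3 and Ank2 (-0.43 ± 0.12) passed. Astrocyte markers rose (9 tested, 2 higher over all genes and 3 adjusted over the list alone, adjusted p = 0.014, adjusted p = 0.17 with an estimated correlation and 0.051 with the batch as a block). Slc1a3 and the growth factor receptor Fgfr3 (0.39 ± 0.11) passed, with the water channel Aqp4 at -0.07 ± 0.09. Fgfr3 passed in only 25 of 51 alternatives and not in batch 1 alone (0.12, adjusted p = 0.38). In batches 1 and 2 alone, the adjusted p was 8.9e-10 and 4.1e-08 for ribosomal proteins, 0.0165 and 0.0032 for cholesterol synthesis, 0.00014 and 0.060 for presynaptic release and 0.119 and 1.8e-05 for transport. It was 0.0199 and 0.705 for synapse-organising factors, 0.0286 and 0.0449 for bound transcripts and 0.461 and 0.0369 for markers. Over all alternatives the adjusted p of these 7 lists lay between 4.5e-14 and 0.705. Of 15 engulfment receptors and machinery genes, through which astrocytes take up synapses, 0 passed with edgeR, either over all genes or adjusted over the list alone. The list did not pass (camera adjusted p = 0.206), with Abca1 at 0.14 ± 0.09 and Rac1 at 0.03 ± 0.11. Members of lists that did not pass as a whole were the elongation factor Eef2 (-0.45 ± 0.11), the neuropeptide precursor Vgf (-0.51 ± 0.13), the guidance factor Sema6a (0.38 ± 0.10) and the Y-linked Eif2s3y (0.68 ± 0.19). Eif2s3y passed in only 27 of 49 alternatives and not in batch 2 alone (0.46, adjusted p = 0.39). Sema6a did not pass in batch 1 alone (0.15, adjusted p = 0.22).

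**Figure D3:**
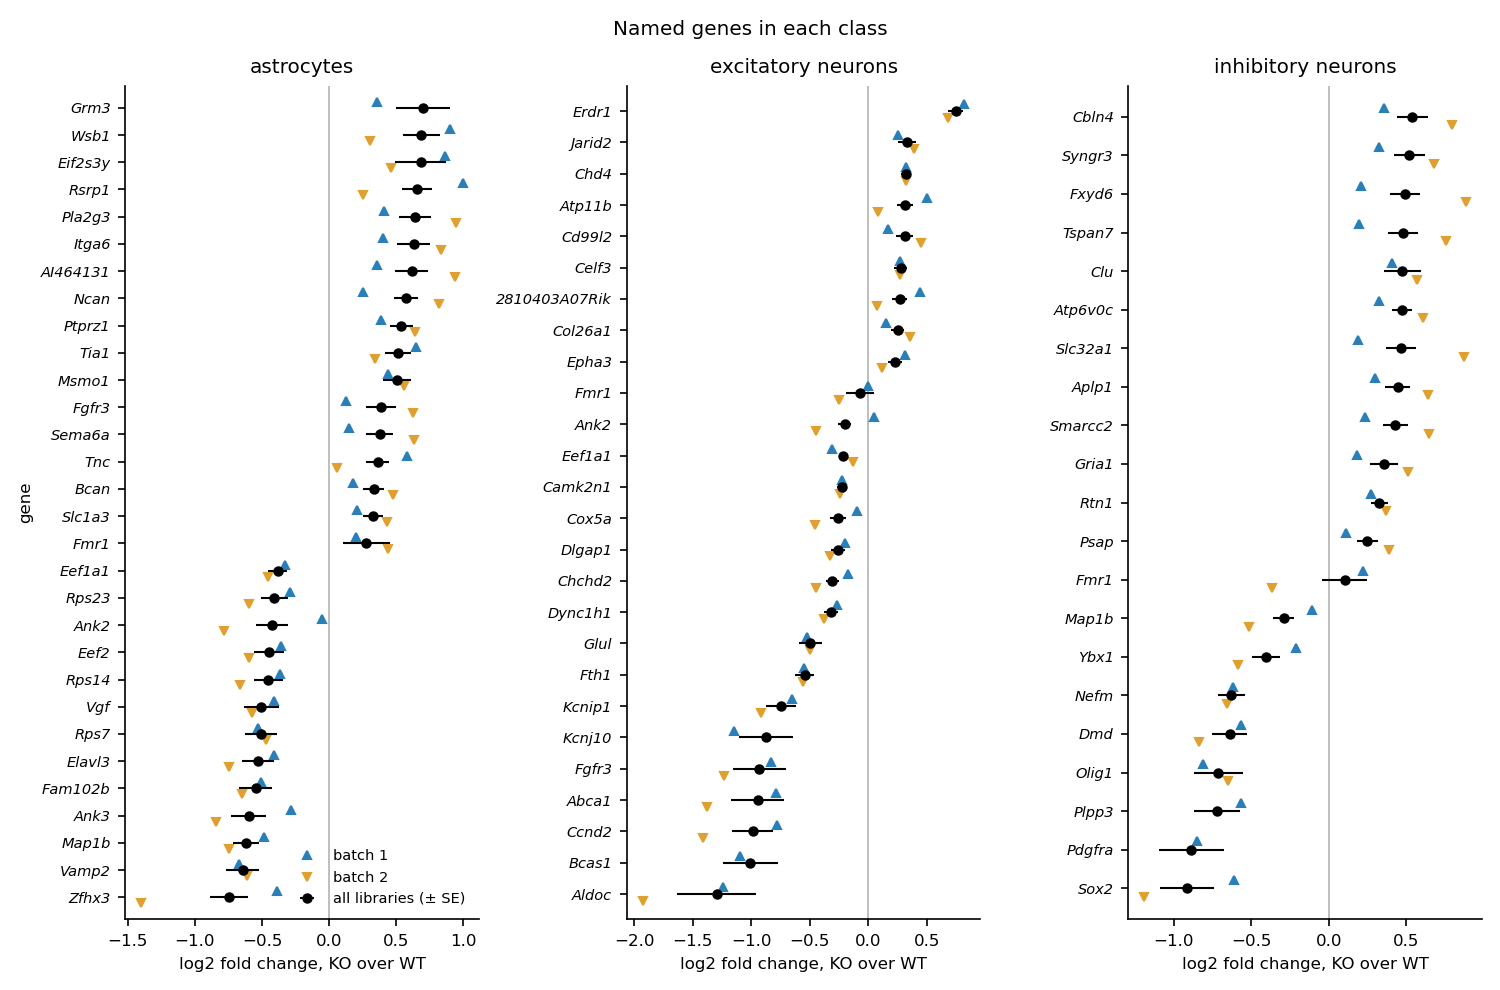
Log2 fold change, KO over WT, of the named genes in astrocytes, excitatory neurons and inhibitory neurons; black dots with bars are all libraries ± SE, and triangles are each batch alone. In astrocytes Map1b lies at -0.48 in batch 1 and -0.75 in batch 2, and Ncan at 0.25 and 0.82.

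Microglia, the phagocytes of the brain, gave 1 gene past the threshold among 140 tested. This was Map1b, which fell from 2424 ± 646 to 1421 ± 696 CPM (-0.83 ± 0.21, n = 15 and 13, adjusted p = 0.034, below the WT median in 11 of 13 libraries labelled KO). Genes of microglial activation and the lysosome rose as a list (median 0.33, 7 tested, 0 past the threshold by edgeR over all genes and 1 adjusted over the list alone, camera adjusted p = 0.00038, and adjusted p = 0.079 with an estimated correlation). Its most abundant members, the lysosomal protease Ctsb (0.35 ± 0.15) and the lipid carrier Apoe (0.31 ± 0.18), did not pass singly. Homeostatic microglial genes rose as a list (median 0.31, 8 tested, 0 past the threshold by edgeR in either adjustment, camera adjusted p = 0.0018, and adjusted p = 0.079 with an estimated correlation). The growth factor receptor Csf1r was at 0.15 ± 0.15 and the purinergic receptor P2ry12 at 0.28 ± 0.21. So did microglial markers (median 0.24, 8 tested, 0 past by edgeR in either adjustment, camera adjusted p = 0.0054, and adjusted p = 0.16 with an estimated correlation). In batches 1 and 2 alone, the adjusted p was 0.00040 and 0.055 for activation, 0.00020 and 0.058 for homeostatic genes and 0.0012 and 0.049 for markers. Over all alternatives the adjusted p of these 3 lists lay between 1.4e-05 and 0.16. Across the 140 genes, which are not independent replicates, fold change correlated with the ratio of abundance in another class to that in microglia (Spearman -0.423). The median was 0.34 for the 30 genes at least 4 times as abundant in microglia and -0.21 for 3 genes as much more abundant in another class. Less RNA of other cells in droplets labelled KO was not separated from a change within microglia. The share of UMIs in genes of inhibitory neurons, KO over WT, was at a ratio of 0.980 in batch 1 (exact p = 0.813) and 0.748 in batch 2 (exact p = 0.275).

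The 9 further microglial genes of smallest p did not pass, with adjusted p from 0.063 to 0.091. Lower in direction were the mRNA-binding Ybx1 (-1.09 ± 0.31), the adaptor Ywhae (-0.81 ± 0.25), the translation factor Eif4g2 (-0.71 ± 0.22), the tubulins Tubb2b (-0.67 ± 0.20) and Tubb2a (-0.50 ± 0.17). Higher in direction were the surface receptor Fcrls (0.42 ± 0.15), the lysosomal protease Ctsl (0.57 ± 0.19), Ly86 (0.64 ± 0.21) and Rsrp1 (0.65 ± 0.22). Of these 9, 8 passed with the batch as a block, with adjusted p from 0.018 to 0.048, and Fcrls did not (adjusted p = 0.060). Neither the 5 engulfment genes (camera adjusted p = 0.162) nor the 8 ribosomal protein genes (camera adjusted p = 0.431) passed as lists. Of their members 0 passed by edgeR, either over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 28 genes by edgeR. With the batch as a block 13 genes passed, 5 higher and 8 lower, Map1b among them. Map1b passed in 27 of 46 alternatives. Its call was lost with DESeq2, without a filter on low counts, without each library's deepest nucleus, in batch 2 alone (adjusted p = 0.34), with 1 value per genotype and batch, and in 14 of 28 fits that each left out 1 library.

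Excitatory neurons, for which only genes up to Lce1a1 in the alphabet were analysed, showed lower levels of astrocyte genes in libraries labelled KO. Aldoc (11:78322968-78327781), a glycolytic enzyme of astrocytes, fell from 112 ± 63.9 to 43.5 ± 30.8 CPM (-1.30 ± 0.34, n = 16 and 16, adjusted p = 0.047). It passed in 29 of 50 alternatives, in which its fold change lay between -1.93 and -0.31, the latter with the share of genes of other classes as a covariate. Chd4 (6:125095981-125130591), a chromatin remodeller of the NuRD complex, rose from 1266 ± 98.5 to 1580 ± 106 CPM (0.32 ± 0.04, adjusted p = 3.6e-06, above the WT median in 16 of 16 libraries). Erdr1 rose most clearly (0.75 ± 0.07, adjusted p = 3.6e-11), but it is a multicopy pseudoautosomal gene that the annotation used here does not place, so its value is uncertain.

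Of 4628 genes tested, 55 passed, 22 higher and 33 lower. With the batch as a block 267 passed, 113 higher and 154 lower, all 55 among them. Of the 33 lower genes, 16 (48.5%) were at least 4 times as abundant in another class, against 5.12% of all genes tested (odds ratio 18.6, 95% interval 8.66 to 39.7). Genes of astrocytes took 1.94% of excitatory UMIs in libraries labelled KO against 2.29% in batch 1 (exact p = 0.00016, n = 8 and 8) and 1.63% against 1.81% in batch 2 (exact p = 0.00078). Astrocyte transport and homeostasis genes fell as a list (median -0.61, 10 tested, 4 lower over all genes and 5 adjusted over the list alone, adjusted p = 8.3e-06, and adjusted p = 0.18 with an estimated correlation). Lower members were Glul (-0.50 ± 0.10), the glutamine synthetase, and the potassium channel Kcnj10 (-0.87 ± 0.23) beside Aldoc, and the list passed in both batches (adjusted p = 1.2e-09 and 7.4e-05). Kcnj10 passed in only 23 of 48 alternatives and had too few counts for a test in batch 2 alone. Other lower genes known from glia or progenitors were the oligodendrocyte gene Bcas1 (-1.01 ± 0.23), the cell cycle gene Ccnd2 (-0.99 ± 0.17), the lipid transporter Abca1 (-0.94 ± 0.22) and Fgfr3 (-0.93 ± 0.23).

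Other genes fell as well. The potassium channel partner Kcnip1 (-0.75 ± 0.13), the ferritin chain Fth1 (-0.54 ± 0.08), the dynein heavy chain Dync1h1 (-0.32 ± 0.06), the postsynaptic scaffold protein Dlgap1 (-0.26 ± 0.06) and the kinase inhibitor Camk2n1 (-0.23 ± 0.04) fell. So did Ank2 (-0.20 ± 0.05), Eef1a1 (-0.21 ± 0.04) and the mitochondrial genes Chchd2 (-0.31 ± 0.05) and Cox5a (-0.26 ± 0.07). Higher genes besides Chd4 were the chromatin regulator Jarid2 (0.33 ± 0.08), the lipid flippase Atp11b (0.31 ± 0.07) and Cd99l2 (0.31 ± 0.07). The others were the splicing regulator Celf3 (0.28 ± 0.06), the collagen gene Col26a1 (0.25 ± 0.06), the guidance receptor Epha3 (0.23 ± 0.06) and 2810403A07Rik (0.27 ± 0.06), a gene of unnamed function. Each named gene past the threshold lay on its side of the WT median in at least 14 of 16 libraries labelled KO. The genes were chosen by p in these libraries and the median pools both batches, so this count is no separate support. Ank2 counts as lower here, though it was not lower in batch 1. Nuclear-encoded genes of mitochondrial respiration fell as a list over all libraries (median -0.13, 13 tested, 1 lower over all genes and 2 adjusted over the list alone, adjusted p = 5.8e-05, and adjusted p = 0.49 with an estimated correlation). In batch 1 this list leaned the other way and did not pass (adjusted p = 0.341), and in batch 2 it was lower (adjusted p = 2.1e-14). Over all alternatives the adjusted p of both lists lay between 2.1e-14 and 0.49. Ank2 had opposite directions in the batches (0.05 in batch 1 and -0.45 in batch 2), and Atp11b rose in batch 1 (0.50) but did not pass in batch 2 (0.08, adjusted p = 0.61). With 1 value per genotype and batch edgeR passed 37 genes, 1 higher and 36 lower (347 at an unadjusted p under 0.05).

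**Figure D4:**
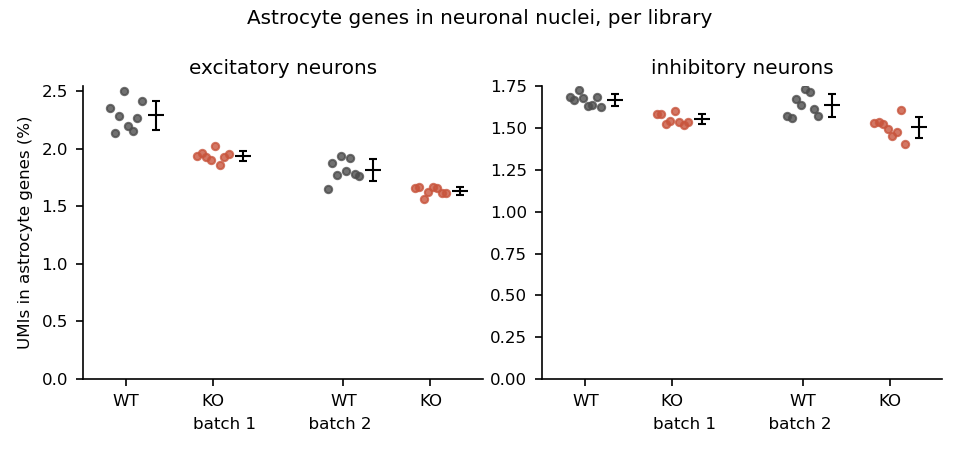
Percent of UMIs that fall in genes at least 4 times as abundant in astrocytes, in excitatory neurons (243 genes) and inhibitory neurons (297 genes); each dot is a library, grouped by batch and genotype word, with mean ± SD. Libraries labelled KO lie lower in each batch, at 1.94% against 2.29% and 1.63% against 1.81% in excitatory neurons.

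In inhibitory neurons Atp6v0c and Slc32a1 rose in libraries labelled KO and Nefm fell. Atp6v0c (17:24163866-24169702), a subunit of the proton pump that acidifies vesicles, rose from 1097 ± 92.1 to 1517 ± 183 CPM (0.47 ± 0.06, n = 16 and 16, adjusted p = 6.7e-06, above the WT median in 16 of 16 libraries). Slc32a1 (2:158610767-158615748), the vesicular GABA transporter, rose from 309 ± 81.1 to 436 ± 50.998 CPM (0.47 ± 0.10, adjusted p = 0.0058). Nefm (14:68082590-68124846), the medium neurofilament chain, fell from 253 ± 37.4 to 163 ± 23.9 CPM (-0.63 ± 0.09, adjusted p = 6.7e-06, below the WT median in 16 of 16 libraries). Its exons overlap those of Nefl on the opposite strand.

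Of 7551 genes tested, 63 passed, 46 higher and 17 lower. In batch 1 alone more genes were lower than higher (443 and 323), unlike in batch 2 (49 and 93). With nuclei thinned to a common depth 16 of 3001 genes tested passed, 10 higher and 6 lower. With the batch as a block 244 passed, 141 higher and 103 lower, all 63 among them. Other higher genes were the synaptic organiser Cbln4 (0.54 ± 0.10), the synaptic vesicle gene Syngr3 (0.52 ± 0.10), the sodium pump regulator Fxyd6 (0.49 ± 0.10), the tetraspanin Tspan7 (0.48 ± 0.10) and the chaperone Clu (0.47 ± 0.12). With them rose the amyloid precursor-like Aplp1 (0.44 ± 0.08), the chromatin remodeller subunit Smarcc2 (0.43 ± 0.08), the AMPA receptor subunit Gria1 (0.35 ± 0.09), the reticulon Rtn1 (0.33 ± 0.06) and the lysosomal precursor Psap (0.25 ± 0.07). Psap passed in only 22 of 51 alternatives and not in batch 1 alone (0.11, adjusted p = 0.19). Lower genes were the progenitor factor Sox2 (-0.91 ± 0.17), the oligodendrocyte precursor genes Pdgfra (-0.89 ± 0.21) and Olig1 (-0.71 ± 0.16) and the lipid phosphatase Plpp3 (-0.72 ± 0.15). Lower too were the dystrophin gene Dmd (-0.64 ± 0.12), Ybx1 (-0.41 ± 0.09) and Map1b (-0.29 ± 0.07). Map1b did not pass in batch 1 alone (-0.11, adjusted p = 0.105). Each named gene past the threshold lay on its side of the WT median in at least 14 of 16 libraries labelled KO. Of the 17 lower genes, 6 (35.3%) were at least 4 times as abundant in another class, against 2.81% of genes tested (odds ratio 19.4, 95% interval 5.82 to 57.9). Genes of astrocytes took 1.56% of UMIs against 1.67% in batch 1 (exact p = 0.00016, n = 8 and 8) and 1.51% against 1.64% in batch 2 (exact p = 0.0017).

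By camera 9 of 24 lists passed in inhibitory neurons, and none of the 9 held with an estimated correlation. Genes of the GABAergic synapse rose (median 0.12, 21 tested, 1 higher in both adjustments, adjusted p = 0.0070, and adjusted p = 0.072 with an estimated correlation). So did genes of interneurons born in the medial ganglionic eminence (median 0.55, 5 tested, 0 past by edgeR over all genes and 3 adjusted over the list alone, camera adjusted p = 0.027, and adjusted p = 0.072 with an estimated correlation). Inhibitory markers rose too (6 tested, 1 higher in both adjustments, adjusted p = 0.027, adjusted p = 0.30 with an estimated correlation and 0.059 with the batch as a block). Nuclear-encoded genes of mitochondrial respiration rose (median 0.08, 26 tested, 0 past by edgeR in either adjustment, camera adjusted p = 0.0043, and adjusted p = 0.30 with an estimated correlation). They were lower in batch 2 (adjusted p = 0.011) and higher in batch 1 (adjusted p = 4.5e-08). Genes of cholesterol synthesis (median 0.15, 19 tested) and of axon guidance and adhesion (median 0.07, 36 tested) rose as lists with 0 members past by edgeR in either adjustment, each at a camera adjusted p = 0.032, and adjusted p = 0.072 with an estimated correlation. The second was at an adjusted p = 0.055 with the batch as a block. Lower lists were astrocyte markers (6 tested, 0 lower by edgeR over all genes and 2 adjusted over the list alone, adjusted p = 0.0070, and adjusted p = 0.22 with an estimated correlation) and markers of oligodendrocyte precursors (5 tested, 2 lower in both adjustments, adjusted p = 0.032, and adjusted p = 0.26 with an estimated correlation). Astrocyte transport and homeostasis genes were lower too (15 tested, 1 lower over all genes, and 1 higher and 3 lower adjusted over the list alone, adjusted p = 0.019, and adjusted p = 0.20 with an estimated correlation). In batches 1 and 2 alone, the adjusted p was 0.210 and 0.0030 for the GABAergic synapse, 0.124 and 0.085 for cholesterol synthesis, 0.051 and 0.306 for axon guidance and 0.0076 and 0.851 for astrocyte transport. In batch 1 it was 0.460 for interneurons of the medial ganglionic eminence, 0.512 for inhibitory markers, 0.00016 for astrocyte markers and 0.011 for markers of oligodendrocyte precursors, which in batch 2 had too few members for a test. Over all alternatives the adjusted p of the 9 lists lay between 4.5e-08 and 0.851. With 1 value per genotype and batch edgeR passed 0 genes (454 at an unadjusted p under 0.05).

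Whether the genotype effect differed between classes was tested within libraries. Astrocytes and excitatory neurons differed in 41 of 4097 genes, 11 with a higher and 30 with a lower fold in excitatory neurons (7 and 35 with median-of-ratios scaling). The fatty acid binding protein Fabp7 led, with a difference in log2 fold of -1.19 ± 0.12 (adjusted p = 6.2e-11). It passed in neither class alone (adjusted p = 0.10 in astrocytes and 0.077 in excitatory neurons). Next came Aldoc (-1.32 ± 0.18), Ccnd2 (-1.39 ± 0.21), Glul (-0.78 ± 0.13) and the acyl-CoA synthetase Acsbg1 (-1.33 ± 0.23), all genes that astrocytes express. Astrocytes and inhibitory neurons differed in 99 of 7594 genes, 56 higher and 43 lower in inhibitory neurons (40 and 68 with median-of-ratios scaling). Among them were Fabp7 (-0.67 ± 0.10), Plpp3 (-0.94 ± 0.15), the tubulin Tubb5 (0.53 ± 0.09) and Aplp1 (0.71 ± 0.13). Of these, Fabp7 and Tubb5 passed in neither class alone. Excitatory and inhibitory neurons differed in 61 of 4656 genes, 39 higher and 22 lower in inhibitory neurons (51 and 16 with median-of-ratios scaling). Of smallest p were Fxyd6 (0.67 ± 0.08), Islr2 (1.40 ± 0.20), Aldoc (1.25 ± 0.19), Atp6v0c (0.30 ± 0.05) and Gpm6a (0.37 ± 0.06). Islr2 passed in neither class alone (adjusted p = 0.27 in excitatory and 0.59 in inhibitory neurons). Microglia differed from inhibitory neurons in 2 of 2879 genes, Apoe (-1.02 ± 0.24) and the interneuron neuropeptide Sst (3.204 ± 0.76), each with adjusted p = 0.032. Sst had too few microglial counts for a test in that class alone and did not pass in inhibitory neurons (adjusted p = 0.27). Apoe passed in neither class alone (adjusted p = 0.33 in microglia and 0.34 in inhibitory neurons). Microglia against astrocytes gave 0 of 1502 genes by edgeR (75 at an unadjusted p under 0.05; 0 by limma-voom and by DESeq2). Microglia against excitatory neurons gave 0 of 3645 (176; 0 by limma-voom and by DESeq2).

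The batches shared only part of the genotype effect. In astrocytes 489 genes passed in batch 1 alone and 197 in batch 2 alone. The counts were 604 and 237 in excitatory neurons, 766 and 142 in inhibitory neurons, and 7 and 0 in microglia, by edgeR. Of genes past the threshold in both batches, astrocytes had 21 higher in both, 27 lower in both and 7 opposite, where independent batches would give 7.36, 7.68 and 15.04. Excitatory neurons had 7, 34 and 30 (8.57, 6.71 and 15.3 if independent), and inhibitory neurons 25, 9 and 3 (4.92, 3.62 and 9.47). A genotype by batch term passed for 127 genes in astrocytes, 438 in excitatory neurons, 266 in inhibitory neurons and 0 in microglia (edgeR, 15 at an unadjusted p under 0.05). Across genes, which are not independent replicates, the fold changes of the batches correlated with r = 0.381 in astrocytes (894 genes of at least 200 CPM), -0.0918 in excitatory neurons (1326) and 0.173 in inhibitory neurons (1017). In microglia r was 0.506 (78 genes).

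**Figure D5:**
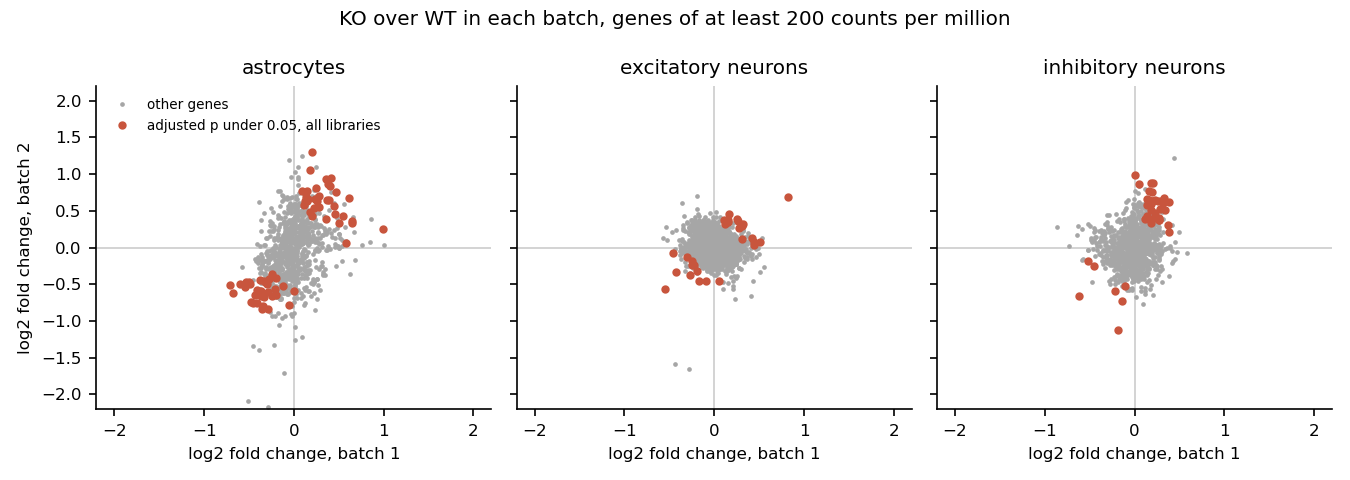
Log2 fold change, KO over WT, in batch 1 (horizontal) against batch 2 (vertical) for genes of at least 200 CPM in 3 classes; red dots are genes with an adjusted p under 0.05 over all libraries, grey dots all others. The red dots were chosen by the fit over both batches, which favours equal directions; over all dots r is -0.0918 in excitatory neurons.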

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

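The tests of explanations, the regroupings of libraries, the fits within a batch and the genotype by batch tests in this part were chosen only after the results were seen, while the search for far libraries and the tests between classes were fixed before. No biological explanation was tested, since the labels assign no GEO sample to a group.

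In 4 of 52 groups of 8 or fewer libraries 1 library lay far from all others of its batch and genotype, and chance marks about 1 in 20 such groups. KO batch 1 replicate 3 had a median of 1106 UMIs per inhibitory nucleus, where the others had 762.5 to 923. KO batch 2 replicate 1 held 1.48% microglia, where the others held 0.529% to 0.868%. KO batch 2 replicate 3 held 14.985% inhibitory neurons (others 11.2% to 12.7%), and its excitatory neurons had 1.56% of UMIs in astrocyte genes (others 1.62% to 1.66%).

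The genotype effect differed between classes, by a test of the difference itself, in 41 genes for astrocytes and excitatory neurons, 99 for astrocytes and inhibitory neurons, 2 for microglia and inhibitory neurons and 61 for excitatory and inhibitory neurons. Against astrocytes, the excitatory fold was lower for Fabp7 (-1.19), Aldoc (-1.32), Ccnd2 (-1.39), Glul (-0.78) and Acsbg1 (-1.33), over the genes analysed for that class, and the inhibitory fold was lower for Fabp7 (-0.67) and Plpp3 (-0.94) and higher for Tubb5 (0.53) and Aplp1 (0.71). Against microglia, the inhibitory fold was lower for Apoe (-1.02) and higher for Sst (3.204), which had too few microglial counts for a test in that class alone. Against excitatory neurons, it was higher for Fxyd6 (0.67), Islr2 (1.40), Aldoc (1.25), Atp6v0c (0.30) and Gpm6a (0.37). Among 21 splits of the libraries, the real one included, only the real split reached the counts of 41 (highest other 27), 99 (31), 2 (0) and 61 (24). That is 1 split each, the fewest that 21 splits can give, with several pairs of classes tested and no adjustment over them. So few splits cannot exclude chance in the grouping of libraries, though no other split reached 41, 99 or 61. Chance between preparations was not tested. The count of 2 for microglia and inhibitory neurons fell to 0 with limma-voom, with DESeq2 and in batch 2, so that it depends on the method. For astrocytes and microglia, all 21 splits reached the real count of 0 (highest other 0). For microglia and excitatory neurons all 21 reached 0 (highest other 2). Chance cannot be excluded for these pairs either.

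The genotype effect differed between the batches, by a test of the difference itself, in 127 genes of astrocytes, 438 of excitatory neurons and 266 of inhibitory neurons. In 100 splits within the batches, only 1, the real one, reached these counts (highest others 25, 10 and 12). Such splits mix the genotypes within each batch, so they also remove any genotype effect common to both batches. They therefore cannot exclude chance for a difference between the batches, and chance between preparations was not tested. For microglia 100 of 100 splits reached the real count of 0 (highest other 9), and chance cannot be excluded either. The share of astrocytes, KO minus WT, was higher in batch 2 than in batch 1 by 5.02 percentage points (permutation p = 0.00016, adjusted p = 0.0013), and that of inhibitory neurons lower, by -4.43 points (permutation p = 0.0023, adjusted p = 0.0093).

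Astrocyte genes were lower in excitatory and inhibitory neurons of libraries labelled KO, in both batches. The greater depth of nuclei labelled KO is argued against as the whole cause in excitatory nuclei, since among nuclei of like depth the share stayed lower. Exact p was 0.0011 and 0.0040 in batches 1 and 2 with 200 to 400 UMIs. It was at most 0.0258 with 100 to 200 or 400 to 800 UMIs. In inhibitory nuclei exact p was 0.00031 and 0.0011 with 500 to 1000 UMIs. With 250 to 500 UMIs it was 0.00093 and 0.535, and with 1000 to 2000 UMIs 0.00062 and 0.108. Depth is thus argued against in inhibitory nuclei in batch 1, and stays open in batch 2. Less RNA from other cells in the droplets labelled KO stays open as a candidate explanation: it needs genes of other classes to be lower as well, and genes of inhibitory neurons were lower in excitatory neurons (KO over WT ratio 0.761 in batch 1 and 0.871 in batch 2), as were genes of excitatory neurons in inhibitory neurons (0.862 and 0.816). Microglial genes were lower in excitatory neurons (0.887 and 0.962) but not lower by an exact test in inhibitory neurons (0.977 and 1.05).

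Some genes more abundant in neurons, such as Elavl3 and Ank3, were lower in astrocytes of libraries labelled KO. Less neuronal RNA in these droplets stays open as a cause. Genes at least 2 times as abundant in neurons, 11 of the 43 lower genes among them, did not fall as a set in astrocytes. Their median log2 fold change was 0.0388 (601 genes, 95% interval 0.00637 to 0.0690), against -0.49 for the 43. But the 43 were chosen for being lower in these same libraries, so this contrast cannot decide the question. A set at least 4 times as abundant (median 0.0451, 20 genes) held 0 of the 43 and excludes nothing. The lower genes were more often of other classes at 2-fold (odds ratio 2.24). The share of UMIs in genes of inhibitory neurons does not decide this. Over all nuclei its log2 ratio was 0.0783 in batch 1 (exact p = 0.115) and 0.0561 in batch 2 (exact p = 0.253). Among astrocyte nuclei of 500 to 1000 UMIs it was -0.124 (exact p = 0.0559) and -0.177 (exact p = 0.0499). It was -0.0319 and -0.0524 with 250 to 500 UMIs, and 0.0822 and -0.00595 with 1000 to 2000 UMIs. A change within the astrocytes and a change in the makeup of the astrocyte nuclei were not tested and stay open.

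Most fold changes of 1 batch were not repeated in the other. Counting error alone is argued against outside microglia: across genes of at least 200 CPM, which are not independent replicates, the batches correlated with r = 0.381 in astrocytes, -0.0918 in excitatory neurons and 0.173 in inhibitory neurons, where equal folds with this error would give about 0.791, 0.772 and 0.760. In microglia r was 0.506, where equal folds would give 0.486, so counting error stays open there. Whether each genotype and batch was 1 preparation of nuclei stays open: the spread between libraries of a group was a median of 1.11 times that after random reassignment of nuclei (1.01 to 1.34 in 12 groups), yet in 10 of the 12 groups it exceeded all 100 reassignments, and both separate animals and separate making of libraries would give that.

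Splits regroup libraries, so they can exclude chance among libraries only. If the libraries of a genotype and batch were parts of 1 preparation, chance between preparations stays untested. Among 100 splits of the libraries, 2 reached the real count of genes in astrocytes (90 genes; highest other 459), 2 in excitatory neurons (55; 639) and 2 in inhibitory neurons (63; 604), so chance among libraries can be excluded. In microglia 3 did (1 gene, highest other 2). That gene passed in only 27 of 46 alternatives, so chance among libraries cannot be excluded there. The highest other splits called several times the real count outside microglia, which points to a structure of the samples: they had 13 of 16 libraries of batch 1 in 1 group, and thus followed the batch (10 in microglia). With the batch as a block and splits within the batches, 1 of 100 splits, the real one, reached the count in each class, at 356 genes in astrocytes (highest other 1), 13 in microglia (2), 267 in excitatory neurons (16) and 244 in inhibitory neurons (11). For gene lists, 3 of 100 splits reached the real count in astrocytes (7 lists; highest other 9) and 1 in inhibitory neurons (9; 7), so chance among libraries can be excluded, but 13 did in microglia (3; 5) and 17 in excitatory neurons (2; 5), where chance cannot be excluded. With the block, splits within the batches that reached the real count of lists were 3 in astrocytes (6 lists; highest other 6), 2 in excitatory neurons (4; 4) and 1 in inhibitory neurons (7; 4), so chance among libraries can be excluded there, but 14 in microglia (3; 4), where it cannot.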

How the results depend on the processing

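The fits within a batch, those with 1 sum per genotype and batch, the library number as a block, the list tests with the batch as a block, the depth test permuted within batches and the share of genes of other classes (the other-class score) were chosen only after the data were seen, and all other alternatives were planned. Of 1608 values of named genes under alternatives, 1369 kept direction and side of the threshold, 200 were no longer past it, 37 were newly past it and 2 turned, and with 1 library left out 2509 of 2762 kept both. Calls of named genes were lost most often with 1 sum per genotype and batch (69), with the other-class score and batch (32), without a filter (29) and in batch 2 (16). Depth limits microglia most, with 140 genes tested. Planned but not run were the tests between classes with 1 library left out and a sex term. The nucleus names give no sex for a library. Too few microglial genes reached a mean of 50 counts for the stricter filter. Except where a number of calls itself shows fewer libraries or genes, the cause was not tested.

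Genes past the threshold numbered, in the order astrocytes (90 as reported), microglia (1), excitatory neurons (55) and inhibitory neurons (63), with only the counts that moved by more than 1.5 times given: 208, 0, 98 and 154 with DESeq2; 10 in microglia with limma-voom and 2 with median-of-ratios scaling; 37, 0 and 33 in the first 3 without a filter; 356, 13, 267 and 244 with the replicate block; 217, 2, 202 and 237 with 1 surrogate variable; 210, 11 and, in inhibitory neurons, 16 with thinned nuclei. Microglia gave 2 with no minimum of nuclei, 7 with at least 30 nuclei and 0 without each library's deepest nucleus. Batch 1 alone gave 489, 7, 604 and 766, and batch 2 alone 197, 0, 237 and 142. With 1 sum per genotype and batch 0 passed in astrocytes, microglia and inhibitory neurons. The other-class score gave 2, 415 and 1120 in microglia, excitatory and inhibitory neurons, and with the replicate block 398, 5, 171 and 0; in inhibitory neurons the median fold of genes past the threshold under the block went from 0.35 to 0.36 for higher genes, from -0.56 to -0.34 for lower genes of other classes and from -0.33 to -0.29 for other lower genes. In excitatory neurons these went from 0.27 to 0.24, from -0.78 to -0.67 and from -0.26 to -0.19. The score correlated with the genotype (r = -0.636 in inhibitory neurons), and why these calls ended was not tested. All zero counts are from edgeR unless DESeq2 is named.

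Lists past the threshold (7, 3, 2 and 9 as reported) numbered 3, 0, 0 and 0 with an estimated correlation, 4 in excitatory neurons with the replicate block, 1 in microglia in batch 2, and in inhibitory neurons 5 with fry, 5 in batch 1 and 2 in batch 2. Differences between classes moved as follows. Astrocytes and excitatory neurons (41) gave 78 in batch 1, 64 with DESeq2 and 106 with the replicate block. Astrocytes and inhibitory neurons (99) gave 197 with a mean of at least 50 counts, 448 in batch 1, 31 in batch 2, 245 with DESeq2, 343 with the replicate block and 306 with 1 surrogate variable. Excitatory and inhibitory neurons (61) gave 100 with a mean of at least 50 counts, 258 in batch 1, 15 in batch 2, 113 with limma-voom, 125 with DESeq2, 119 with the replicate block and 28 with thinned nuclei. Astrocytes and microglia (0) gave 1 in batch 2. Microglia and excitatory neurons (0) gave 5 in batch 1, 4 with at least 30 nuclei, 2 with thinned nuclei, and 1 each with a mean of at least 50 counts, the replicate block and 1 surrogate variable. Microglia and inhibitory neurons (2) gave 0 in batch 2, with limma-voom, with DESeq2, without a filter, with at least 30 nuclei and without each library's deepest nucleus.

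Directions turned for Ank2 in excitatory neurons in batch 1 (0.0479), Atp11b in excitatory neurons with the other-class score and block (-0.0179), and Fmr1 in excitatory neurons with the score (0.25) and in inhibitory neurons with the score (-0.22) and in batch 2 (-0.37). The list of mitochondrial respiration turned in batch 1 in excitatory neurons (adjusted p = 0.341) and in batch 2 in inhibitory neurons (adjusted p = 0.0107), and that of axon guidance in batch 2 in inhibitory neurons (adjusted p = 0.306). Differences of shares in batch 2 were 1.28, -0.00685, -0.122 and -1.15 percentage points in astrocytes, microglia, excitatory and inhibitory neurons, all turned, and in batch 1 -3.75 in astrocytes and 3.29 in inhibitory neurons, both past the threshold. Among nuclei of at least 500 UMIs they were -4.99, -0.348, 13.6 and -8.26, the first 3 now past the threshold (adjusted p = 0.0242, 0.0381 and 0.0466), though this limit keeps more of the deeper excitatory nuclei labelled KO, and the log2 ratio of microglia to excitatory neurons was -0.0250. Differences in depth were, in batch 1, 46.9 UMIs and 37.1 genes in astrocytes, both now past the threshold, and 17.8 genes in microglia, and 102 UMIs in inhibitory neurons, no longer past the threshold; in batch 2, -23.8 genes in astrocytes and -54.0 genes (now past the threshold) and -24.4 UMIs in microglia; 15.1 genes in microglia with means over nuclei; and 67.1 genes in inhibitory neurons permuted within batches (replicate block), now past the threshold.

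With 1 library left out, genes past the threshold ranged from 67 to 101 in astrocytes, 0 to 8 in microglia, 36 to 74 in excitatory neurons and 39 to 63 in inhibitory neurons. Libraries that moved a count by more than 1.5 times were KO batch 2 replicate 4 in excitatory neurons (36), KO batch 2 replicate 1 in inhibitory neurons (39), and in microglia KO batch 2 replicates 2, 5 and 6 and WT batch 2 replicate 3 (8, 2, 2 and 6) and those without which it was 0, namely KO batch 1 replicates 1, 2, 3, 5, 7 and 8, WT batch 1 replicates 3, 5 and 6 and WT batch 2 replicates 2, 4, 6, 7 and 8. Lists ranged from 6 to 8, 3 to 3, 2 to 4 and 3 to 11 in the 4 classes; KO batch 1 replicates 2 and 5 and WT batch 2 replicates 5 and 8 moved the excitatory count, and KO batch 1 replicates 1, 3, 4, 6 and 8 and WT batch 1 replicates 1 to 8 the inhibitory count. Fmr1 ranged from 0.23 to 0.36 in astrocytes, -0.12 to -0.04 in excitatory and 0.01 to 0.16 in inhibitory neurons. Shares ranged from -1.82 to -0.794, -0.0457 to 0.0457, -0.870 to 1.16 and 0.300 to 1.87 points, UMIs from 18.5 to 30.7, -9.79 to 10.2, 134 to 148 and 115 to 150, and genes from -0.756 to 14.3, -13.2 to 0.567, 81.7 to 90.8 and 50.3 to 80.2.

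The replicate block, with the preset correlation for lists, changed no other call than those given here and in the report among counts of genes, lists and shares. The block with an estimated correlation is not given here for the lists. The library numbers within a batch pair nothing: deviations of same-numbered libraries correlated with medians of -0.00409, -0.0833, 0.0113 and 0.0120, and 3, 0, 5 and 3 libraries labelled WT correlated best with their own number. With that number as the replicate block the counts were 268, 7, 225 and 178.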

Other observations

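The genes of the next paragraphs were chosen after their values were seen, as those past the threshold in more than 1 class, and the counts over pairs of classes were chosen only after the results were seen. Map1b was lower in all 3 classes in which it was analysed, astrocytes (-0.62 ± 0.09), microglia (-0.83 ± 0.21) and inhibitory neurons (-0.29 ± 0.07), and comes later in the alphabet than the genes analysed in excitatory neurons. Map1b did not pass in inhibitory neurons in batch 1 alone (-0.11, adjusted p = 0.105) or in microglia in batch 2 alone (-0.94, adjusted p = 0.34). Eef1a1 (-0.38 ± 0.07 and -0.21 ± 0.04) and Ank2 (-0.43 ± 0.12 and -0.20 ± 0.05) were lower in both astrocytes and excitatory neurons. Chd4 was higher in both (0.38 ± 0.10 and 0.32 ± 0.04), as was Erdr1 (1.06 ± 0.23 and 0.75 ± 0.07), whose position is uncertain. Nefm was lower in both astrocytes (-0.65 ± 0.17, adjusted p = 0.027) and inhibitory neurons (-0.63 ± 0.09), and the flippase Atp9a was higher in both excitatory (0.28 ± 0.07, adjusted p = 0.025) and inhibitory neurons (0.35 ± 0.09, adjusted p = 0.038).

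Other genes had opposite directions. Ccnd2 was higher in astrocytes (0.46 ± 0.13, adjusted p = 0.034) and lower in excitatory neurons (-0.99 ± 0.17), and so was Fgfr3 (0.39 ± 0.11 and -0.93 ± 0.23). Ptprz1 (0.54 ± 0.09 and -0.46 ± 0.12) and Plpp3 (0.38 ± 0.09 and -0.72 ± 0.15) were higher in astrocytes and lower in inhibitory neurons, and the neuronal vesicle gene Nsg2 was lower in astrocytes (-0.36 ± 0.10) and higher in inhibitory neurons (0.51 ± 0.10).

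Shared calls were few beside the genes tested, though mostly more than independent calls would give. Of 1887 genes tested in astrocytes and excitatory neurons, 2 were higher in both (0.141 if the calls were independent), 2 lower in both (0.318) and 2 opposite. Of 3994 tested in astrocytes and inhibitory neurons, 0 were higher in both by edgeR (0.381), 2 lower in both (0.151) and 3 opposite, and of 3315 tested in excitatory and inhibitory neurons 1 was higher in both (0.132), 1 lower in both (0.0416) and 0 opposite. With the batch as a block, 8 were higher and 22 lower in both astrocytes and excitatory neurons (2.85 and 4.92), 6 and 19 in both astrocytes and inhibitory neurons (4.43 and 3.72), and 12 and 9 in both kinds of neurons (1.69 and 1.61). Of 121 genes tested in astrocytes and microglia, 1 was lower in both (0.116). With the block, 1 was higher in both (0.248), 8 lower in both (2.58) and 0 opposite by edgeR. The classes come from the same libraries, so a library's batch and free RNA are common to the values compared.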
